A study of Mus musculus with 2 samples.

How the data were processed

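RNA was measured in 2 libraries from cultures labelled as mouse neonatal cardiomyocytes, 1 from cells given a negative control and 1 from cells given an antagomir against the piRNA FERPIR. Groups were taken from the sample titles. A further treatment label reads PBS for both samples and was not used. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was isolated with magnetic beads and libraries were made with a KAPA stranded kit. The same protocol then lists adaptor ligation at both RNA ends, a step of small RNA libraries, so the library type is not settled by it. FERPIR had no value in the table used here, which held protein-coding genes. The deposited table held gene-level FPKM values, which per the submitters' processing notes came from a workflow with cutadapt, HISAT2 and StringTie version 1.3.3 on genome build GRCm38. The annotation release, the trimming and alignment settings and whether fragments were assigned by strand are not given in the sources used here. FPKM divides by transcript length and by the library total, so a library that holds more of a few abundant genes shows lower values for all others.

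The table had 10992 genes, all of them labelled protein coding, and in every one the higher of the 2 FPKM values was above 0.5. A gene without a value can be low in both libraries or missing for another reason, since the table used here may hold only part of the genes, so a missing value is not read as low expression. For 10 symbols on more than 1 line the FPKM values were summed, which left 10982 genes. Listed at 0 were 14 genes in the control and 10 in the antagomir library, which can be failed estimates, and no fold is given against them. Steps of whole reads were searched for in low FPKM values multiplied by transcript length, and none were found in either library, so the depth of both libraries is unknown and intervals or detection limits that need it were not computed.

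With 1 library per group there was no test, p-value, SD between replicates or standard error, and all values describe these 2 libraries. The log2 ratio was log2 of (antagomir FPKM + 1) over (control FPKM + 1), a scale that understates differences of low genes, and folds are on the same scale. Genes with at least 1 FPKM in the higher library were counted at a 2-fold limit. For 40 gene lists covering cardiac function, cell death, iron, stress, cell cycle, metabolism, inflammation, matrix, RNA pathways, library quality and other cell types, the median log2 ratio was set against 10000 random lists of the same size matched on deciles of mean expression. A list was said to lie outside below percentile 2.5 or above 97.5, and lists with fewer than 5 usable members were given as values. Members at least 1.5-fold higher or lower were also counted. Gene lists, limits, the rule for named genes and all but 4 of the alternatives were chosen before the data were examined.

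The rule named, first, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes reaching 5 FPKM, leaving out predicted loci, pseudogenes and histone genes. It named, second, in each list up to 2 members at either end that reached 5 FPKM, and any member that reached 1 FPKM with a 2-fold difference. It also named Myh6, Tnnt2, Col1a1, Pecam1, Ptprc, Hba-a1 and Actb as checks of the cells, whatever their values. This gave 212 genes, of which the text prints a part. Outside the rule, chosen after their values were seen, are Eif3j1, Gpx4, Slc7a11, Fabp4, Lyz2, Nkx2-5, Casp4, Ankrd1, Des, Lgals1, S100a4 and the histone genes.

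Transcript lengths, GC content and overlaps of exons came from GENCODE release M21 on the same genome build, in which 10987 gene identifiers were found. The authors' own annotation can differ from it. Length and GC content were those of the longest annotated transcript of each gene, which can differ from the transcripts behind the FPKM. Since strand use is not stated, genes whose exons overlap on either strand were treated as uncertain. The scripts ran in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. They were tested on simulated values for 10301 genes. The changed genes were drawn from those with a mean of at least 5 FPKM and shifted on the scale of FPKM + 1. Recovery of lower genes was therefore not simulated. All of 50 genes per direction set 4-fold apart, and all of 50 set 8-fold apart, passed the 2-fold limit. So did 431 genes simulated without a set change. Their spread, an SD of 0.484, was taken from the observed log2 ratios, which hold any real differences too, so this number is no measured chance rate. Of 400 simulated lists without a shift 6.8% lay outside the random lists, and of 50 lists shifted by 0.5 on the log2 scale 96.0% lay above them. Simulated genes varied independently, so these shares do not hold for lists whose genes vary together.

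Alternatives were pseudocounts of 0.1 and 0.01, a minimum of 0.1 or 5 FPKM or none, rescaling to TPM, by a trimmed mean of log ratios, by the median log2 ratio, or without mitochondrially encoded, hemoglobin and ribosomal protein genes, the highest value in place of the sum for repeated symbols, limits of 1.5-fold and 4-fold, random lists without matching, and list means in place of medians. The 4 added later removed the trend over transcript length and GC content, matched random lists on length, or left out genes with overlapping exons or members of the integrated stress response list.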

Results

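Gene expression was measured by RNA sequencing in cultures labelled as neonatal mouse cardiomyocytes, the contractile muscle cells of the newborn heart. The cells had received either a negative control or an antagomir, a chemically modified antisense oligonucleotide, against the piRNA FERPIR. A piRNA is a short RNA of the class that PIWI proteins bind. There were 2 libraries, 1 per group. The table of gene values listed 10992 protein-coding genes in FPKM, fragments scaled to transcript length and to the library total. The values summed to 295404 FPKM in the control library and 312806 FPKM in the antagomir library, with medians of 6.74 and 6.31 FPKM per gene. The number of reads behind them is unknown, so no counting interval is given, and no difference between the libraries has a replicate check. FERPIR had no value in the table used here, so the knockdown itself was not measured.

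The comparison asked how the gene expression profile of the cells differed after FERPIR knockdown. Genes of the unfolded protein response and of the integrated stress response had lower FPKM in the antagomir library, with median log2 ratios of -1.22 over 22 genes and -0.94 over 28 genes. Mitochondrially encoded genes had a median log2 ratio of -1.04 and extracellular matrix genes one of -0.44. Genes of the G2 and M phases of the cell cycle had higher FPKM, with a median log2 ratio of 0.62 over 30 genes, as had those of DNA replication, with 0.51 over 31 genes. The sarcomere genes Tnnt2 and Tnnc1 were 3.71-fold and 3.69-fold higher, from low control levels of 1.48 and 4.39 FPKM. Among 10201 genes with at least 1 FPKM in the higher library, 294 were at least 2-fold higher and 387 at least 2-fold lower in the antagomir library, on the scale of log2(FPKM + 1). At 4-fold these counts were 7 and 31. The median log2 ratio of these genes was -0.05, its SD across genes was 0.55, and Pearson's r between the libraries was 0.95 across genes, which are not independent replicates. At 2-fold, 492 genes were higher and 635 lower with a pseudocount of 0.1, 388 and 724 as TPM, and 446 and 709 after rescaling without mitochondrially encoded, hemoglobin and ribosomal protein genes, and centring on the median turned the balance to 355 higher and 346 lower. Values as TPM and after the rescaling without these families are larger throughout, so the pseudocount of 1 weighs less in them.

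**Figure D1:**
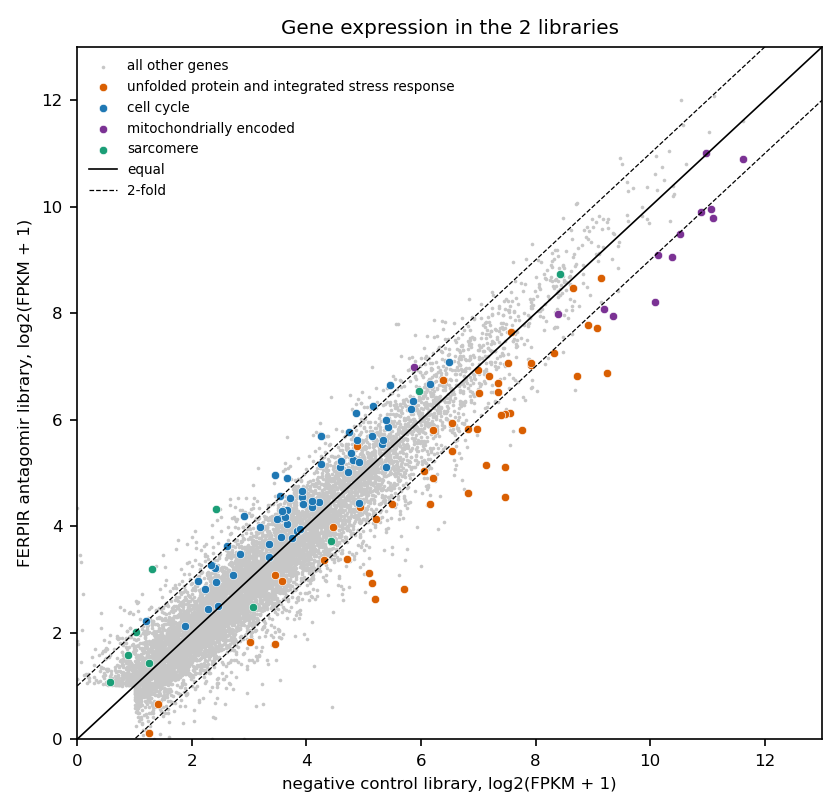
Each point is 1 gene, with log2(FPKM + 1) in the negative control library on the x axis and in the FERPIR antagomir library on the y axis (1 library each). Dashed lines mark 2-fold differences; stress response genes (orange) lie mostly below the diagonal, with medians of -1.22 and -0.94 for the 2 lists, and cell cycle genes (blue) mostly above it, with medians of 0.62 and 0.51.

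Ranked by log2 ratio among genes reaching 5 FPKM, the lower end of 12 genes held Atf3, Gdf15, Ddit3 and Sel1l, members of the 2 stress response lists. Atf3, a stress-induced transcription factor, had 176 FPKM in the control library and 22.5 FPKM in the antagomir library, a log2 ratio of -2.91. Gdf15, a secreted stress-induced cytokine, had 50.9 and 6.06 FPKM, a log2 ratio of -2.88. Ddit3, which encodes the pro-apoptotic factor CHOP, had 609 and 117 FPKM, 5.16-fold lower, although its exons overlap those of Mars. Sel1l, a component of endoplasmic reticulum-associated degradation, was 5.90-fold lower. Also at this end, beside protocadherin genes, were Cdsn (6.69-fold lower), Cpeb4 (5.95-fold), Ak4 (5.41-fold) and Emp1 (5.15-fold), and, with exons overlapping those of another gene, Myadm (5.78-fold) and Prg4 (5.65-fold). At the upper end Crip1 had 46.5 FPKM in the control and 222 FPKM in the antagomir library, 4.70-fold higher, and Fam107b was 3.91-fold higher. Tnnt2 and Tnnc1 also stood at this end.

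In coordinates of mouse genome build GRCm38, Atf3 lies on chromosome 1 from 191170296 to 191218039, Gdf15 on chromosome 8 from 70629393 to 70632456, Ddit3 on chromosome 10 from 127290774 to 127296288, Crip1 on chromosome 12 from 113146316 to 113153879 and Tnnt2 on chromosome 1 from 135836354 to 135852260. Several genes at both ends share exons or sequence with other genes, and their values are uncertain. Eif3j2 was listed at 0 in the control library and had 19.2 FPKM in the antagomir library, and it has a close copy, Eif3j1, with 19.9 and 15.2 FPKM. Exosc6 (0.03 and 9.95 FPKM) overlaps exons of Aars, Ccdc85b (47.7 and 222 FPKM) overlaps Fosl1, Nup62 (7.93 and 33.0 FPKM) overlaps Atf5, and Tuba4a (5.35 and 21.9 FPKM) overlaps Stk16. The protocadherin genes Pcdhga7, Pcdhga3 and Pcdhgc3 were at the upper end and Pcdhga2 and Pcdhgb4 at the lower end, Pcdhgb4 being listed at 0 in the antagomir library; all 5 share their last exons. Exons of 231 of the 681 genes with a 2-fold difference overlapped those of another gene.

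Of the 40 gene lists, 34 had at least 5 members with values, and the medians of 14 lay outside the central 95% of 10000 random lists of matched expression, 9 below and 5 above. This percentile describes these 2 libraries only. The limits leave 5% of random lists outside by construction, and 6.8% of 400 simulated lists without a shift lay outside. Both shares are for genes that vary independently, whereas genes of a pathway can vary together between any 2 cultures. Neither is therefore a chance rate for these lists.

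**Figure D2:**
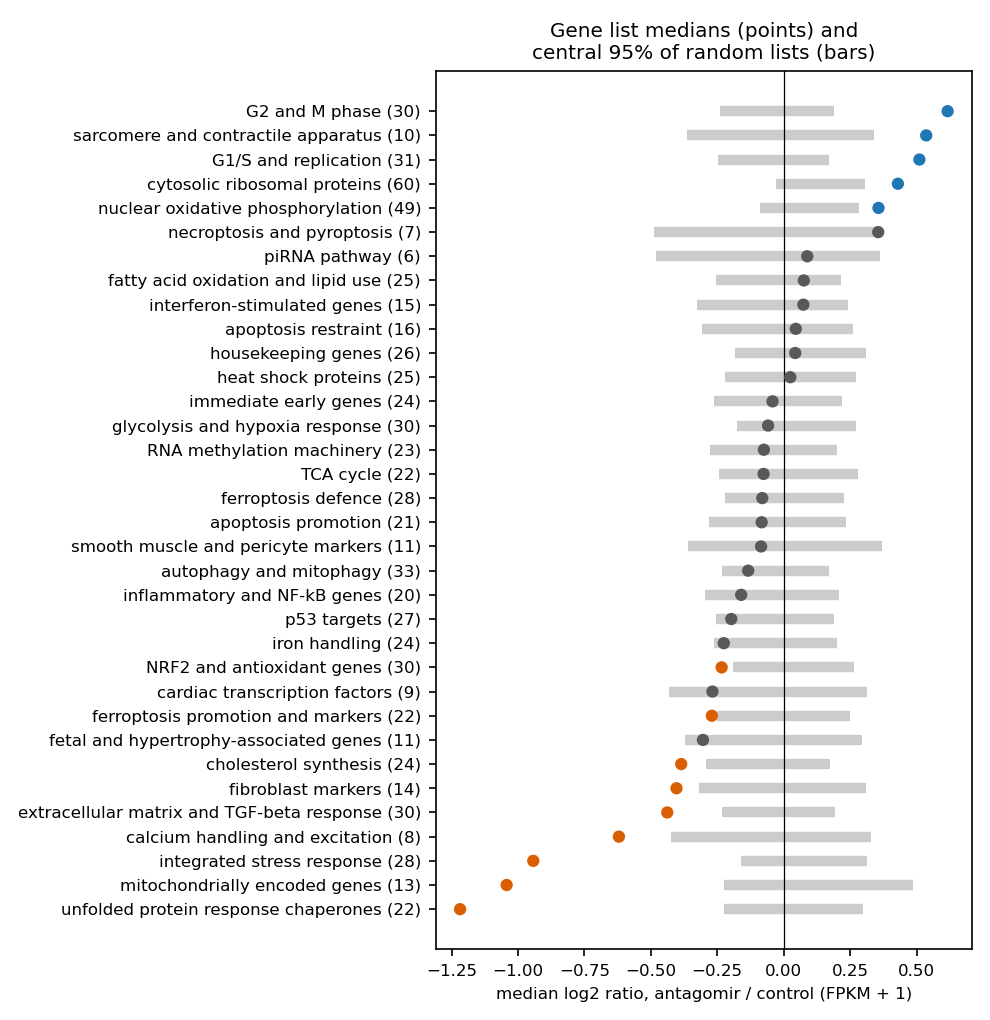
Points show the median log2 ratio of FPKM + 1, antagomir over control (1 library each, x axis), of each gene list with at least 5 members used (number in brackets), and grey bars the central 95% of medians of 10000 random lists matched on expression. The 9 orange points lie below their bars, the lowest at -1.22 for unfolded protein response chaperones, and the 5 blue points lie above, the highest at 0.62 for the G2 and M phase list.

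The unfolded protein response list, chaperones and degradation factors induced when proteins misfold in the endoplasmic reticulum, had 19 of 22 members at least 1.5-fold lower, 15 of them at least 2-fold lower, and none 1.5-fold higher. Hspa5, the main chaperone of this compartment, had 483 FPKM in the control and 218 FPKM in the antagomir library, 2.21-fold lower. Calr was 3.75-fold lower, Hyou1 3.91-fold lower and Herpud1, with 176 and 33.4 FPKM, 5.14-fold lower. Sec61b, a subunit of the translocation channel, was the single member with a log2 ratio above 0, at 0.36, but at -0.21 with the trend over transcript length and GC content removed. The list's median lay at percentile 0.00 of the random lists. In the integrated stress response list, targets of the translation-control pathway through ATF4, 18 of 28 members were at least 1.5-fold lower and 1, Ddit4, was higher, at 1.53-fold. Chac1, a glutathione-degrading enzyme, was 3.96-fold lower, and the amino acid transporter genes Slc3a2 and Slc7a5 were 2.59-fold and 2.47-fold lower. Atf5 had 189 and 199.7 FPKM, with exons that overlap those of Nup62 and a log2 ratio that turned from 0.08 to -0.18 with the trend removed. This list's median also lay at percentile 0.00. The heat shock list, cytosolic chaperones for the most part, had a median log2 ratio of 0.03 over 25 genes at percentile 53.5, with Hspb6 2.09-fold lower and Hspb2 2.10-fold higher, both overlapping other genes and Hspb2 at a log2 ratio of 0.38 with the trend removed.

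All 30 genes of the G2 and M phase list had log2 ratios above 0, except that Ect2 and Prc1, near 0, turned negative under 2 of 4 rescalings, and 17 were at least 1.5-fold higher, 6 of them at least 2-fold. Cdk1, the kinase that drives entry into mitosis, had 34.7 FPKM in the control and 75.7 FPKM in the antagomir library, 2.15-fold higher. Birc5 was 2.38-fold higher, Cdca3 2.85-fold and Bub1b 2.04-fold, whereas Ect2 had 12.5 and 12.8 FPKM. In the list for the G1/S transition and replication, 13 of 31 genes were at least 1.5-fold higher and none was 1.5-fold lower. E2f2 was 2.04-fold higher, and Ccnd1 (18.1 and 50.8 FPKM), Tk1 (11.6 and 29.1 FPKM) and Gins2 (6.49 and 17.3 FPKM), each overlapping another gene, were 2.72-fold, 2.39-fold and 2.45-fold higher. Mcm2, a subunit of the replicative helicase, had 29.0 and 20.7 FPKM, a log2 ratio of -0.47. Both list medians lay above those of all 10000 random lists. The p53 target list had a median of -0.20 at percentile 8.09, within the random lists, with 11 members at least 1.5-fold lower, among them Gdf15 and Sesn2, and 5 higher, among them Phlda3 at 2.03-fold. This list lay outside by its mean, -0.31 at percentile 0.60, and by its median with the trend over transcript length and GC content removed, -0.29 at percentile 0.49. It shares Ddit4, Gdf15 and Sesn2 with the integrated stress response list. Without these, and with the trend left in, its median was -0.19 at percentile 9.30. Among genes that promote apoptosis the median was -0.08 and the mean 0.03 over 21 genes, at percentile 35.6 for the median, with Bbc3 1.73-fold lower and Casp8 1.98-fold higher. Genes that restrain apoptosis had a median of 0.05 over 16 genes at percentile 69.1, with 2 members at least 1.5-fold higher, Birc5 and Bcl2l1 (1.82-fold), and 2 lower, Bcl2l2 (2.21-fold) and Pim1 (1.61-fold), both overlapping predicted genes. The necroptosis and pyroptosis list had a median of 0.36 over 7 genes at percentile 97.4, with Mlkl 1.51-fold and Il18 1.60-fold higher and Casp4 1.53-fold lower, but a mean of 0.07 at percentile 76.8, and a median of 0.02 at percentile 53.2 with the trend removed.

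**Figure D3:**
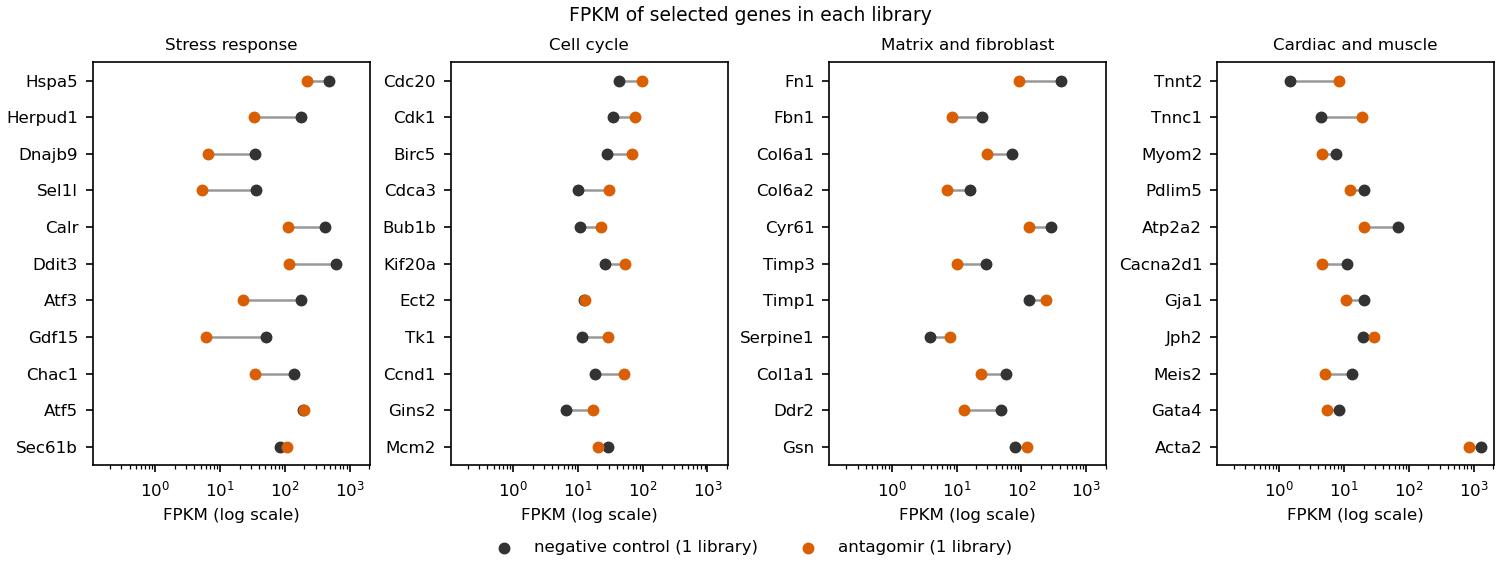
FPKM on a log scale (x axis) of selected genes in the negative control library (dark points) and the antagomir library (orange points), 1 library each, with a line joining the values of each gene. Atf3 reads 176 and 22.5 FPKM, Cdk1 34.7 and 75.7 FPKM, Fn1 414 and 92.8 FPKM, and Tnnt2 1.48 and 8.19 FPKM in the control and antagomir library.

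Of the 13 genes encoded in mitochondrial DNA, 10 were at least 1.5-fold lower in the antagomir library, 8 of them at least 2-fold, and their share of all FPKM was 6.11% in the control and 3.13% in the antagomir library. mt-Nd2 had 1084 and 296 FPKM, 3.66-fold lower, and mt-Cytb, a subunit of complex III, had 2147 and 997 FPKM, 2.15-fold lower. mt-Co2 had 2002 and 2065 FPKM, a log2 ratio of 0.05 that was -0.49 with the trend over transcript length and GC content removed. mt-Nd6, which overlaps mt-Nd5 on the opposite strand, was 2.18-fold higher, with 57.5 and 127 FPKM. The list's median of -1.04 lay at percentile 0.00. Nuclear genes of oxidative phosphorylation had a median log2 ratio of 0.36 over 49 genes at percentile 99.7, with 16 members at least 1.5-fold higher, among them Ndufb3 (2.44-fold) and Ndufa5 (2.32-fold), and 1, Cox6a2, lower. Genes of cytosolic ribosomal proteins had a median of 0.43 over 60 genes at percentile 99.99, with Rpl38 2.45-fold and Rps29 2.47-fold higher, and took 9.94% of all FPKM in the control and 12.8% in the antagomir library. Across genes the log2 ratio was lower for longer transcripts, with Spearman's rho of -0.30 and a median of 0.26 in the shortest and -0.20 in the longest of 5 equal groups of genes. With this trend removed the oxidative phosphorylation median was 0.11 at percentile 95.6, inside the random lists. The ribosomal protein median was then 0.23 at percentile 99.99. The length used was that of the longest annotated transcript, which for Rps20 is 3706 nucleotides, and its log2 ratio went from 1.23 to 1.35. Such lengths may not be those of the mRNAs measured, so the removal does not rule out a length trend for this list. Of the genes named for a 2-fold difference 29 came under it with the trend removed, among them mt-Nd6 (a log2 ratio of 0.59), Rpl38 (0.63), Ifi27l2a (0.64), Phlda3 (0.67), Cisd1 (0.73), Ndufa5 (0.75), Ndufb3 (0.76), Ccl7 (0.79) and Rps29 (0.79).

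**Figure D4:**
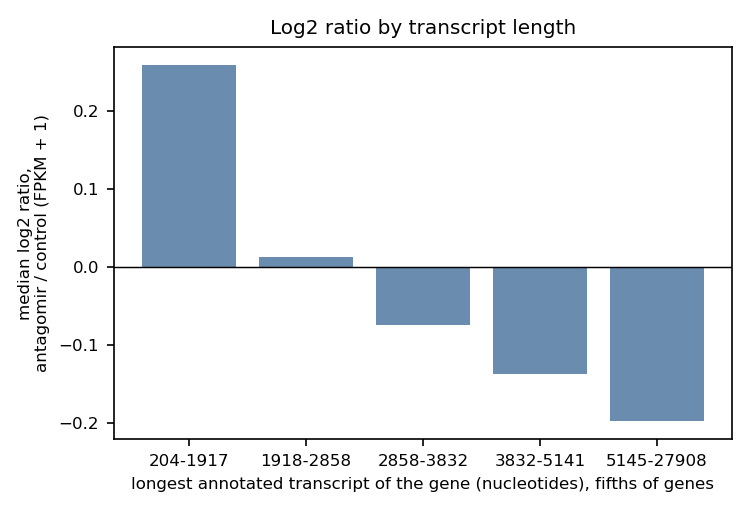
Bars show the median log2 ratio of FPKM + 1, antagomir over control (1 library each), in 5 equal groups of genes ordered by the length in nucleotides of their longest annotated transcript. The median is 0.26 in the group with the shortest transcripts and -0.20 in that with the longest.

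In other metabolic groups, cholesterol synthesis genes had a median log2 ratio of -0.39 over 24 genes at percentile 0.21, with 8 members at least 1.5-fold lower. Sqle, which makes squalene epoxide, had 45.5 and 19.6 FPKM, 2.26-fold lower, Fdft1, which overlaps Ctsb, was 2.57-fold lower, and Pmvk was 1.83-fold higher. Glycolysis and hypoxia genes had a median of -0.06 over 30 genes at percentile 18.5, but 7 members were at least 1.5-fold lower, among them Ero1l, an oxidase of protein folding in the endoplasmic reticulum (186 and 45.1 FPKM), Hk2 (41.4 and 16.4 FPKM) and Vegfa (46.3 and 20.4 FPKM), and 1 was higher, Ankrd37 (1.15 and 3.75 FPKM), which overlaps Ufsp2. Fatty acid oxidation genes had a median of 0.08 and a mean of -0.06 over 25 genes, at percentile 78.9 for the median, with Acot2 2.80-fold lower. Genes of the TCA cycle had a median of -0.08 over 22 genes at percentile 22.9, with Dlst 2.85-fold lower and Sdhb 1.54-fold higher.

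Genes that promote or mark ferroptosis, an iron-dependent cell death by lipid peroxidation, had a median log2 ratio of -0.27 over 22 genes, with 9 at least 1.5-fold lower and 1 higher. Ptgs2, a marker of this death, had 44.0 and 10.2 FPKM, 4.02-fold lower. Acsl4, which activates polyunsaturated fatty acids to their CoA esters, was 2.73-fold lower. Hmox1, which releases iron from heme, was 3.54-fold lower, with 194 and 53.9 FPKM. Genes of ferroptosis defence had a median of -0.08 over 28 genes at percentile 24.8, with 5 at least 1.5-fold lower and 1 higher. Among them Slc3a2 was 2.59-fold lower, Gch1 2.27-fold lower and Cisd1 2.04-fold higher. Fads1, 2.67-fold lower, and Keap1, at a log2 ratio of 0.58, are on this list too. Whether these 2 genes act in defence is uncertain and was not tested, so their values are not read as weaker or stronger defence. The lipid peroxide reductase gene Gpx4 had 455 and 427 FPKM and the cystine transporter gene Slc7a11 had 1.64 and 0.57 FPKM, both chosen after their values were seen. Iron handling genes had a median of -0.23 over 24 genes at percentile 4.97, with 4 at least 1.5-fold lower, among them Hmox1, and 2 higher, among them Iscu (1.68-fold). Antioxidant genes of the NRF2 list had a median of -0.23 over 30 genes at percentile 1.05, with 7 at least 1.5-fold lower, among them Gpx3 (2.44-fold) and Gsta4 (2.03-fold), and 2 higher, Sod1 (1.56-fold) and Txn1 (1.70-fold), but this median lay inside random lists drawn without matching on expression. The promotion list lay at percentile 1.86, and without Atf3 and Chac1, which it shares with the integrated stress response list, its median was -0.22 at percentile 6.10, inside the random lists. With the trend over transcript length and GC content removed its median was -0.09 at percentile 23.4. By its mean the promotion list lay outside, at -0.58 and percentile 0.00, with Atf3 and Chac1 included and the trend not removed.

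Extracellular matrix and TGF-beta response genes had a median log2 ratio of -0.44 over 30 genes at percentile 0.00, with 13 at least 1.5-fold lower and 5 higher. Fn1, which encodes fibronectin and overlaps Apol7d, had 414 and 92.8 FPKM, 4.42-fold lower, and the collagen genes Col6a1 and Col6a2 were 2.35-fold and 2.14-fold lower. Cyr61, a matricellular protein gene, was 2.17-fold lower, whereas Timp1, a metalloproteinase inhibitor gene, had 131 and 240.4 FPKM, 1.83-fold higher. Fibroblast markers had a median of -0.40 over 14 genes at percentile 0.59, with 5 at least 1.5-fold lower, among them Col1a1 (58.5 and 24.2 FPKM) and Ddr2 (49.3 and 13.1 FPKM, overlapping another gene), and Gsn 1.51-fold higher. Removal of the length and GC trend gave a fibroblast median of -0.26 at percentile 3.88, inside the random lists.

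Sarcomere genes had a median log2 ratio of 0.54 over the 10 of 28 listed genes with values, at percentile 99.8, with 4 at least 1.5-fold higher and 2 lower, and a median of 0.43, inside the random lists, for members reaching 5 FPKM. Besides Tnnt2 and Tnnc1, which encode cardiac troponin subunits, Pdlim5 was 1.63-fold and Myom2 1.51-fold lower. Myh6, the main myosin heavy chain gene of the mouse heart, had no value in the table used here, which does not show that it was low. Calcium handling and excitation genes had a median of -0.62 over 8 genes at percentile 0.26, with 18 of 27 listed genes without a value. Atp2a2, which encodes the calcium pump SERCA2 and overlaps a predicted gene, had 67.5 FPKM in the control library and was 3.26-fold lower, Cacna2d1 was 2.18-fold and Gja1 1.77-fold lower, and Jph2 was 1.49-fold higher. With the trend over transcript length and GC content removed, Cacna2d1 came under the 2-fold limit, at a log2 ratio of -0.93. Genes of the fetal and hypertrophy list had a median of -0.30 over 11 genes at percentile 5.98, with Gdf15 and Fgf21 (2.19-fold) at least 2-fold lower and Nppb, which encodes B-type natriuretic peptide, at 6.86 and 5.28 FPKM. Cardiac transcription factors had a median of -0.27 over 9 genes at percentile 13.5, with 4 members above 0 and 5 below. Gata4 had 8.30 and 5.41 FPKM, Nkx2-5 13.7 and 16.4 FPKM, and Meis2 was 2.35-fold lower, whereas Esrra, which overlaps Trmt112, was 1.95-fold higher.

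Endothelial, leukocyte, erythroid, epicardial and neural markers were mostly without values. By contrast, 15 of 21 fibroblast markers and 12 of 17 smooth muscle and pericyte markers had values. Smooth muscle and pericyte markers had a median of -0.09 over 11 genes at percentile 31.6, with Acta2 at 1304 and 845 FPKM and Tagln, which overlaps Pcsk7, 2.02-fold higher. Of the endothelial list 1 of 20 genes had a value, Fabp4, at 0.75 and 1.40 FPKM, and Pecam1 had none. Of the macrophage and leukocyte list 2 of 20 had values, Cd14 (13.6 and 17.5 FPKM) and Lyz2 (3.28 and 4.44 FPKM), and Ptprc had none. Of the erythroid list 3 of 14 had values and a median of 0.97, with Hba-a1 at 10.2 and 11.5 FPKM (a log2 ratio of -0.40 with the trend removed) and Hba-a2, a near-identical copy, at 4.22 and 9.23 FPKM. Krt19 (22.4 and 20.1 FPKM) and Msln (16.6 and 9.80 FPKM) were among 3 epicardial and mesothelial markers with values, whose median was -0.15. Tubb3 (20.1 and 29.0 FPKM) was 1 of 2 Schwann and neural markers that reached 1 FPKM, with a median of 0.41.

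The inflammatory and NF-kB list had a median log2 ratio of -0.16 over 20 genes at percentile 18.7, with members on both sides. The chemokine genes Ccl2 (21.8 and 55.4 FPKM) and Ccl7 (56.3 and 143 FPKM) were 2.47-fold and 2.51-fold higher, and Csf1 was 2.61-fold lower. With the trend over transcript length and GC content removed, Ccl2 and Ccl7 came under 2-fold, at log2 ratios of 0.98 and 0.79. Interferon-stimulated genes had a median of 0.07 over 15 genes at percentile 80.4, with Ifi27l2a 2.22-fold higher and Ifit3 1.77-fold lower. Among immediate early genes, whose median was -0.04 over 24 genes at percentile 44.7, 7 were at least 1.5-fold lower, among them Klf4 (2.85-fold) and Myc (2.49-fold), and 2 higher, among them Junb (2.09-fold), which overlaps Prdx2. Junb came under 2-fold, at a log2 ratio of 0.80, with the trend removed. Genes of the piRNA pathway had a median of 0.09 over the 6 of 26 genes that reached 1 FPKM, at percentile 78.1, with Tdrd7 at 5.56 and 6.15 FPKM. RNA methylation genes had a median of -0.07 over 23 genes at percentile 39.9, with 4 at least 1.5-fold lower, among them Ythdf3 (2.10-fold), and 2 higher, Hnrnpc (1.70-fold) and Hnrnpa2b1 (1.56-fold). Autophagy and mitophagy genes had a median of -0.13 over 33 genes at percentile 16.9, with 5 at least 1.5-fold lower, among them Lamp1 (2.07-fold), which overlaps Grtp1, and none higher. Housekeeping genes had a median of 0.04 and a mean of -0.07 over 26 genes, at percentile 44.2 for the median, with Actb, which encodes beta-actin, 2.03-fold lower at 689 and 339 FPKM. Of the list of nuclear-retained and small structured RNAs, none had a value in the table used here, which held protein-coding genes.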

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

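Chosen only after the data were seen were removal of the trend over transcript length and GC content, random lists matched on length, leaving out genes with overlapping exons, and leaving out members of the integrated stress response list. No paired analysis was possible because each group had 1 library. Against 294 higher and 387 lower genes at 2-fold, counts were 492 and 635 with a pseudocount of 0.1, 524 and 676 with 0.01, 1104 and 1364 at 1.5-fold, and 7 and 31 at 4-fold, where the smaller pseudocount or the limit itself sets the count. They were 446 and 709 after rescaling without mitochondrially encoded, hemoglobin and ribosomal protein genes. Rescaling to TPM gave 388 and 724. Both of these rescalings raise all values while the pseudocount stays at 1, which by itself raises such counts. They also set the totals they use equal between the libraries, which the pseudocount does not do. The median log2 ratio of genes was -0.12 as TPM and -0.10 without these families, against -0.05 as reported. Trend removal gave 195 and 357 (35.3% higher), and leaving out genes with overlapping exons 186 and 264. The share of higher genes among those at 2-fold ranged from 34.9% to 50.6% over the 4 rescalings, against 43.2% as reported. No list outside the random lists reversed its sign under any alternative run. The ferroptosis promotion list came inside the random lists with medians of -0.23 at a minimum of 0.1 FPKM or none, -0.34 as TPM, -0.32 after rescaling without the abundant families, -0.27 with unmatched or length-matched random lists, -0.0885 with the trend removed and -0.22 without integrated stress response members. Other lists that came inside were sarcomere genes at a minimum of 5 FPKM (0.43, with fewer genes), NRF2 genes with unmatched random lists (-0.23), oxidative phosphorylation genes with the trend removed (0.11) or length-matched lists (0.36), and fibroblast markers with the trend removed (-0.26) or length-matched lists (-0.40). Lists inside that came outside were interferon genes at a minimum of 5 FPKM (0.49), necroptosis genes under a trimmed mean (0.40), median centring (0.41) and the highest value per symbol (0.36) but not with the trend removed (0.02), the p53 list by its mean (-0.31) or with the trend removed (-0.29), the fetal list by its mean (-0.50) or with length-matched lists (-0.30), and the glycolysis and autophagy lists by their means (-0.24 and -0.23). Where no construction is named, the cause was not tested. Of the values of named genes under alternatives, 2224 stayed on their side of the limit, 55 no longer passed it, 40 newly passed it and 13 turned in sign. These 13 were Fhl1, Ect2, Prc1, mt-Co2 and Atf5 as TPM (-0.0019 to -0.0476), Ect2, Prc1 and mt-Co2 after rescaling without the abundant families (-0.0058 to -0.0221), and Pebp1 (-0.0155), mt-Co2 (-0.49), Sec61b (-0.21), Atf5 (-0.18) and Hba-a1 (-0.40) with the trend removed. Depth is unknown, so its effect on low genes is open.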

Other observations

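Of the 45 histone genes reaching 1 FPKM, 35 were at least 1.5-fold higher in the antagomir library and 0 lower, with a median log2 ratio of 0.99, and this family was picked after its values were seen. Hist1h2ap had 98.4 and 160.2 FPKM in the control and antagomir library, Hist1h2ao 81.2 and 154 FPKM, and Hist1h4i 4.09 and 15.3 FPKM. Replication-dependent histone mRNAs are short and made in S phase, and several copies are near identical, so their single values are uncertain. Most of these mRNAs lack a poly(A) tail, while per the protocol polyadenylated RNA was isolated. A difference in that selection between the libraries was not tested and cannot be told apart from a difference in S phase. With the trend over transcript length and GC content removed, the family's median was 0.40 and 15 members were at least 1.5-fold higher. In the protocadherin gamma cluster, whose members share their last exons, 5 genes were at least 1.5-fold higher and 3 lower, while their FPKM summed to 32.6 in both libraries. The copies Eif3j1 and Eif3j2 together had 19.9 and 34.4 FPKM.

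Tests chosen only after the result was seen were those of normalization between the libraries, of transcripts over 2000 bases, and all 3 on cardiomyocyte transcripts. The stress response genes were lower in the antagomir library, with a median log2 ratio of -1.07 over the 50 members of the unfolded protein and integrated stress response lists pooled. A trend over transcript length and GC content was argued against, since its removal left a median of -0.99, below the lower bound of -0.17 of random lists. Normalization by a library-wide factor was argued against too, since over 4 rescalings the pooled median lay between -1.20 and -1.02. With a median log2 ratio of -0.05 over all genes, such a factor could move it little. These rescalings shift all genes nearly alike, so a fault that differs between genes was not tested by them. A difference between the cultures other than the antagomir, such as handling, cell density or a stronger response to the control transfection, cannot be told apart from the antagomir with 1 library per group. A lower stress response after FERPIR knockdown therefore stays a hypothesis that may or may not hold in further cultures.

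Shorter transcripts were higher in the antagomir library, with a Spearman's rho of -0.30 across genes, which are not independent replicates. Without 330 genes of ribosomal proteins, oxidative phosphorylation, histones and mitochondrial DNA rho was -0.27, so these families do not account for the trend. Within 5 equal groups by GC content the rho closest to 0 was -0.20, and among 7980 genes with transcripts over 2000 bases it was -0.16, which argues against GC content and against the shortest transcripts alone. A difference in RNA integrity or fragment size between the libraries might give such a trend, but with 1 library per group and no coverage along transcripts analysed here it cannot be told apart from an effect of the antagomir. The lists of oxidative phosphorylation, fibroblast and ferroptosis promotion genes came inside the random lists once this trend was removed, whereas those of stress, cell cycle and mitochondrially encoded genes stayed outside.

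Few transcripts of contractile cardiomyocytes had values in either library. Over the 10 sarcomere genes with values, the median of the higher FPKM was 7.79, below the 90th percentile of all genes at 57.9 FPKM, which argues against contractile cardiomyocytes supplying most of the RNA, as far as these genes go, since the other 18 of 28 listed had no value in the table used here and are not shown to be low. A minority of such cells supplying the cardiac transcription factors stays open. The median FPKM of these sarcomere genes was 0.32 times that of 9 cardiac transcription factors in the control library. In the antagomir library it was 1.18 times that of these factors. Des, among these sarcomere genes, is also on the smooth muscle list, so this ratio does not reflect cardiomyocytes alone. Genes that are abundant here include Lgals1 (2223 and 4332 FPKM), S100a4 (1484 and 4125 FPKM), Acta2 (1304 and 845 FPKM), Ankrd1 (644 and 518 FPKM) and Des (345 and 423 FPKM), and Nkx2-5, a cardiac transcription factor, had 13.7 and 16.4 FPKM. The 14 fibroblast markers that reached 1 FPKM cannot tell apart cardiomyocytes without contractile genes, fibroblasts and smooth muscle cells. Their number could not decide this, since dedifferentiated cardiomyocytes may also make the collagens among them. What such cells make was not tested here. Fibroblasts or smooth muscle cells alone would leave the Nkx2-5 values unexplained, but 1 gene does not give the share of cardiac muscle cells.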
